A study of Oryza sativa with 9 samples.

How the data were processed

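RNA from dehulled rice seeds, taken 10 to 14 days after flowering from plants grown at 27 °C with 12 h of light and 12 h of darkness, was sequenced from 9 libraries, 3 biological repeats of each of 3 genotypes. The libraries were made from total RNA with the ScriptSeq v2 kit, per the labels. The deposited table gives RPKM (reads scaled to transcript length and to the mapped total), which the authors computed for 31263 loci in each library, with 1 column per library and no scaling between libraries beyond the mapped total. The aligner, the read counter, the genome build and the annotation release are not given in the sources used here, and coordinates are those printed in the table.

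RPKM values of 1 locus step in whole reads, so the mapped total of each library, the length of each locus and the read number behind each value were derived from the table. All 281367 values came out as whole reads within a tolerance of 0.001. As a check, none of the 2880 genes with at least 100 reads in every library stayed whole when the totals were replaced by decoys (0.0% against 100.0%). In a simulated table of 5901 genes the same procedure recovered 9 of 9 library totals, 90.4% of lengths and 99.8% of read numbers. The derived totals ran from 5778627 to 18449248 mapped reads. A single read in a transcript of 1 kb was worth between 0.054 and 0.173 RPKM, so the precision of low values differed between libraries by that factor. Reads without molecular identifiers are not independent molecules, and such limits cover counting error only.

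Genes with an RPKM of at least 1 in at least 3 libraries were tested (15450, leaving 15813 untested). Values were transformed to log2(RPKM + 1) and fitted with limma 3.58.1 (trend and robust empirical Bayes) in R 4.3.3, with all 9 libraries in 1 fit. The 3 pairwise comparisons and a joint test of any difference among the genotypes were two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Per-gene p values given below are these adjusted values, and ± denotes the SD over n = 3 libraries unless SE is written. Read shares per gene list were compared by exact permutation tests over all 280 splits of the 9 libraries, and for each pair of genotypes over the splits of 6 libraries, where 3 against 3 cannot give a p below 0.1.

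Gene lists were fixed by locus before the data were examined, as were the comparisons, the tests, the rule for named genes and most of the alternatives. The lists were glutelins, prolamins, globulins with seed albumins of the RAG type, starch synthesis, ER folding and quality control, and endosperm transcription factors. A further 14 lists defined only by words of a gene description could not be filled, because the table holds no descriptions. For 8 of these topics or related ones, lists of loci were written after the table was opened but before their values were looked at (embryo and aleurone, green tissue, alpha-amylases, heat shock proteins, cell division, control genes, gibberellin, and glutelin trafficking and processing). Lists with at least 5 tested members were tested with camera of limma at a preset correlation of 0.01 and, beside it, with the correlation estimated from the data. The Benjamini-Hochberg correction ran over 18 tests of fixed lists and, separately, 18 tests of added lists.

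Gene names are not in the table. They were assigned to loci from general knowledge of the rice literature when the lists were written. The RefSeq gene table at hand shares no identifiers with the loci. Of 52 names given to loci of the fixed lists, 22 occur in it, 22 of them on the same chromosome and 0 only on another one. Loci outside the lists carry their identifier alone, and at most 2 rising and 2 falling ones are printed per comparison.

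Named genes were chosen by rule. They are OsTudor-SN and the loci with the largest changes among called genes. For these loci the 3 libraries of 1 genotype all lay above the 3 of the other, with a mean of at least 5 RPKM. From each fixed list, the rule took the 3 called members with the smallest adjusted p and the 2 with the highest mean. Genes printed from the added lists were not chosen by this rule. The rule asked for described genes among the largest changes, which could not be applied without descriptions. Some genes chosen by the rule are not printed.

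For genes called between EM1084 and wild type, the change remaining in the complemented line was the fitted complemented minus wild type difference as a percentage of the EM1084 minus wild type difference. Both differences share libraries, so values with no complementation, full complementation and no difference at all were obtained from 10 simulations each. On simulated tables with 200 changed genes, limma recovered 61.2% of genes changed 2-fold between EM1084 and wild type, 59.7% between the complemented line and EM1084 and 66.7% between the complemented line and wild type. Unchanged genes made up 8.3%, 6.6% and 7.1% of the respective calls.

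The alternatives tried were quantile normalization, median-of-ratios scaling, library sizes from reads outside the 3 storage protein lists, no filter on low values, a pseudocount of 0.1, a replicate block, fits of 6 libraries only, a fold limit of 1 on the log2 scale, and leaving out each library in turn. Chosen after the table was opened were median-of-ratios scaling of RPKM for the counts of called genes, limma-voom on the derived reads, estimated correlations of lists under each scaling, reads thinned to the smallest library, and the prolamin list without a pair of overlapping loci. Simulations, tables and plots used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9. No sample or value column was left out.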

Results

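Transcripts were profiled in developing seeds of 3 rice genotypes, each with 3 biological repeats. They were the wild type, the mutant line EM1084, whose OsTudor-SN protein (an RNA-binding protein with staphylococcal nuclease and Tudor domains) carries the change E503K, and a transgenic line of EM1084 that received a wild type copy of OsTudor-SN, called the complemented line here. Mapped reads numbered 10551055, 9249133 and 5778627 in the wild type libraries, 12805472, 15167217 and 15630870 in EM1084, and 18051574, 18449248 and 17022681 in the complemented line. Between 91.7% and 94.0% of them fell in listed genes. Even numbers made up 54.5% to 68.2% of the values of 1 to 20 reads, so reads need not be independent fragments. Of the 15450 genes tested, 14368 differed among the genotypes in the joint limma test on RPKM as deposited. This count depended on scaling. It was 10765 under median-of-ratios scaling, 10525 under quantile normalization, 12624 with library sizes outside the storage lists and 9871 with limma-voom.

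Storage protein transcripts took most of the reads in listed genes in wild type and a smaller part of them in both other lines. The 3 storage protein lists together took 59.2% ± 2.3 of the reads in listed genes in wild type, 34.3% ± 0.37 in EM1084 and 47.5% ± 2.5 in the complemented line (SD, n = 3; two-sided exact permutation p = 0.00357 over 280 splits, the smallest they can give). Glutelins, the main storage proteins of the rice endosperm, took 37.7% ± 2.1, 27.2% ± 0.22 and 36.6% ± 1.7 in the same order (exact permutation p = 0.0179). Prolamins, which are stored in bodies formed from the endoplasmic reticulum (ER), took 17% ± 0.094, 5.39% ± 0.44 and 8.33% ± 0.8, and globulins with seed albumins took 4.49% ± 0.25, 1.71% ± 0.16 and 2.59% ± 0.093 (both exact permutation p = 0.00357). Starch synthesis genes took 2.85% ± 0.12, 3.78% ± 0.12 and 4.09% ± 0.16, and ER folding genes 0.662% ± 0.031, 1.09% ± 0.076 and 0.258% ± 0.02 (both exact permutation p = 0.00357). Each pair of genotypes differed in these 6 shares with an exact permutation p of 0.1, the smallest that 3 against 3 allows, except the glutelin share of the complemented line against wild type (p = 0.5).

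**Figure D1:**
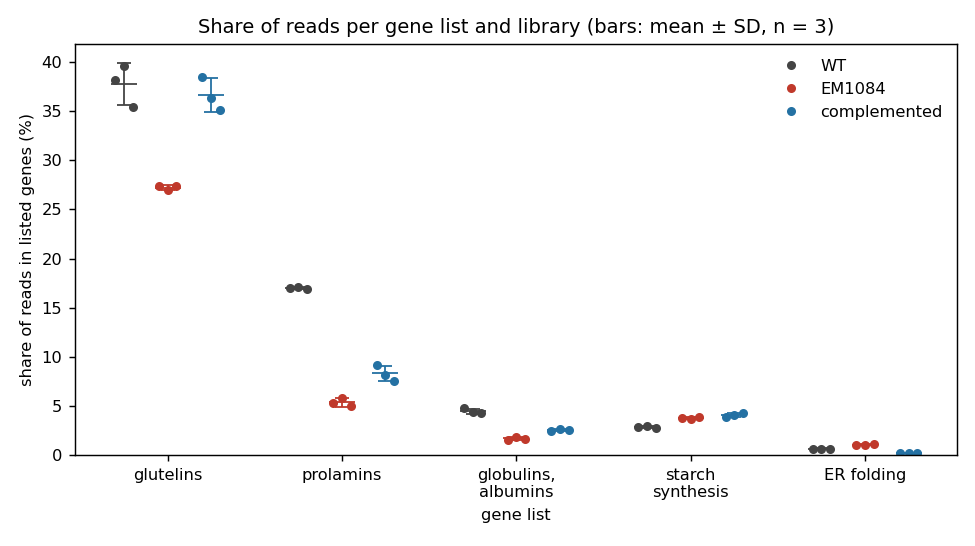
Share of the reads in listed genes (percent, vertical axis) taken by each gene list (horizontal axis) in every library, with points for libraries and bars for the mean ± SD of 3 libraries per genotype. The prolamin share was 17% in wild type, 5.39% in EM1084 and 8.33% in the complemented line.

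RPKM values are relative to the mapped total of a library. The median log2 fold change over all tested genes was 1.06 for EM1084 against wild type, -0.34 for the complemented line against EM1084 and 0.73 for the complemented line against wild type. Scaling by the median of ratios brought these medians to 0.10, -0.01 and 0.10, and scaling on reads outside the storage protein lists brought them to 0.58, -0.08 and 0.50. To the log2 fold change of an abundant gene median-of-ratios scaling added -1.38, 0.42 and -0.96 in the 3 comparisons, and scaling outside the storage lists added -0.69, 0.33 and -0.37, so the folds below are folds of RPKM as deposited. Changes of gene lists are given below relative to the median of all genes, and scalings are named where a direction differs.

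**Figure D2:**
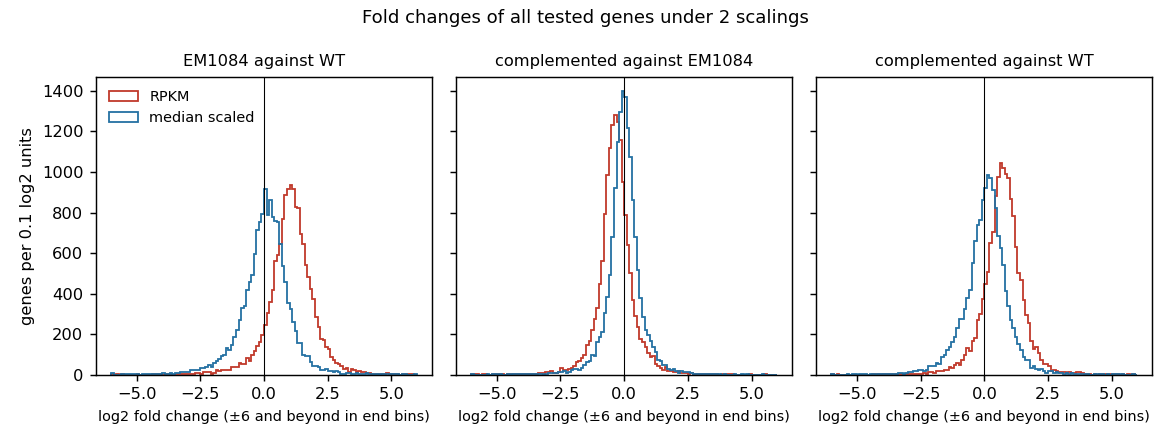
Histograms of the log2 fold changes of all 15450 tested genes (horizontal axis; vertical axis, genes per 0.1 log2 units) in the 3 comparisons, from RPKM as deposited and after median-of-ratios scaling. The median of EM1084 against wild type moved from 1.06 to 0.10.

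The first question was which seed transcripts differ between the Tudor-SN mutant and the wild type. Storage protein genes were mostly lower in EM1084, although the glutelin direction flipped under quantile normalization. GluA1 (LOC_Os01g55690, chromosome 1, 32076732 to 32078743), a glutelin gene, fell from 34900 ± 2080 to 15400 ± 201 RPKM (log2 fold change -1.18, SE 0.06, adjusted p = 2.2e-09), and GluA2 (LOC_Os10g26060) fell from 29200 ± 1890 to 13900 ± 81.3 RPKM. Of 12 glutelin genes 8 fell, 2 rose and 2 did not pass, and their median lay at -1.76 relative to all genes (camera adjusted p = 5.3e-14; adjusted p = 0.075 with an estimated correlation). Under quantile normalization 8 glutelin genes were higher and 2 lower, whereas median-of-ratios scaling gave 12 lower and scaling outside the storage lists 11 lower and 1 higher. Quantile normalization gives every library the same set of values. It thus removes a difference in the share of reads taken by the most abundant genes as a group. The highest in EM1084, LOC_Os02g15169, stood at 34500 ± 2640 RPKM in wild type and 32700 ± 1790 in EM1084 (adjusted p = 0.33), and was called lower under median-of-ratios scaling (log2 fold change -1.45, adjusted p = 2.1e-08) and outside the storage lists (-0.76, adjusted p = 4e-05).

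Of 23 prolamin genes 15 fell and 6 rose, with a median of -2.11 relative to all genes (camera adjusted p = 1.2e-23; adjusted p = 0.00071 with an estimated correlation). More fell than rose under every scaling tried, but with an estimated correlation the list's call was lost outside the storage lists (adjusted p = 0.061). The prolamin locus with the smallest adjusted p, LOC_Os06g31060, rose from 0.277 ± 0.259 to 52.2 ± 4.48 RPKM (log2 fold change 5.4, SE 0.14, adjusted p = 5.3e-12). It rose under median-of-ratios scaling too (4.63). LOC_Os07g10570, next by adjusted p, fell from 18700 ± 263 to 3670 ± 81 RPKM (log2 fold change -2.35, SE 0.07, adjusted p = 1.2e-11). The most abundant prolamin locus, LOC_Os05g26386, fell from 51700 ± 10800 to 19900 ± 2500 RPKM, and LOC_Os05g26377, listed over nearly the same stretch (chromosome 5, 15338152 to 15338822, against 15338155 to 15338822), from 15200 ± 11700 to 29.1 ± 8.75 RPKM. The wild type values of the second locus were 20400, 23400 and 1690 RPKM, while the pair summed to 65300, 69300 and 65800 RPKM, so the split between them is uncertain. Its log2 fold change of -8.31 (SE 1.03) moved to -7.65 without wild type 2 and -9.54 without wild type 3. Among 9 globulin and albumin genes 6 fell and 3 rose (median -2.38 relative to all genes, camera adjusted p = 8.8e-10; adjusted p = 0.075 with an estimated correlation), and 4 rose and 4 fell under quantile normalization. RAG2 (LOC_Os07g11380), a seed albumin gene, fell from 9710 ± 669 to 1480 ± 130 RPKM (adjusted p = 1.3e-11), alpha-globulin (LOC_Os05g41970) fell from 13300 ± 792 to 8250 ± 832 RPKM, and RAG1 (LOC_Os07g11360), a neighbour of RAG2, rose from 4.53 ± 1.19 to 276 ± 15.3 RPKM (log2 fold change 5.67, SE 0.13, adjusted p = 2.9e-12).

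Of 9 tested genes of ER folding and quality control, 8 rose in EM1084 and BiP1 fell, next to 12781 of all 15450 genes called higher. The list did not pass as a list, with a median 0.80 above that of all genes (camera adjusted p = 0.074; adjusted p = 0.46 with an estimated correlation), and this median was 0.53 without EM1084 3 and 0.40 under median-of-ratios scaling. Under quantile and outside-storage scaling 9 and 8 members were higher, and under median-of-ratios scaling 5 were higher, 1 lower and 3 did not pass. ERO1 (LOC_Os03g52340), the oxidase that recharges disulfide isomerases, rose 4.52-fold from 19.2 ± 0.731 to 86.9 ± 4.03 RPKM (adjusted p = 1.9e-10). The disulfide isomerase genes PDIL1-1 (LOC_Os11g09280) and PDIL2-3 (LOC_Os09g27830) rose 4.22-fold, from 487 ± 22.6 to 2050 ± 164 RPKM, and 4.3-fold, from 34.7 ± 4.35 to 149 ± 6.7 RPKM. Under median-of-ratios scaling the log2 fold changes of ERO1, PDIL1-1 and PDIL2-3 were 0.78, 0.69 and 0.72. BiP1 (LOC_Os02g02410), an ER chaperone of the HSP70 family, stood at 1870 ± 106 RPKM in wild type and 1640 ± 111 in EM1084. Its log2 fold change was -0.19 (adjusted p = 0.049) on RPKM as deposited and -1.57 under median-of-ratios scaling. Under quantile normalization BiP1 was among the 9 members called higher, so its direction depended on scaling. On RPKM as deposited its call was lost with a replicate block (adjusted p = 0.063) and without wild type 1 (0.13), wild type 2 (0.15), EM1084 1 (0.14), EM1084 2 (0.14) or complemented 2 (0.058).

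Of 25 starch synthesis genes 17 rose and 2 fell, but their median lay at -0.36 relative to all genes (camera adjusted p = 0.19; adjusted p = 0.64 with an estimated correlation), and the direction flipped to 4 higher and 17 lower under median-of-ratios scaling and to 7 higher and 8 lower outside the storage lists. The sucrose synthase genes SUS3 (LOC_Os07g42490) and SUS1 (LOC_Os03g28330) rose from 48.9 ± 1.3 to 186 ± 10.5 RPKM and from 2.44 ± 0.599 to 19 ± 0.504 RPKM, under median-of-ratios scaling too (log2 fold change 0.54 and 1.40). AGPL1 (LOC_Os05g50380), a large subunit of ADP-glucose pyrophosphorylase, fell from 73.3 ± 3.22 to 19.1 ± 0.907 RPKM (log2 fold change -1.89, SE 0.10, adjusted p = 2.2e-09). The small subunit gene AGPS2 (LOC_Os08g25734), the most abundant of the list, was 2360 ± 131 and 2760 ± 125 RPKM, with a log2 fold change of 0.22 that turned to -1.15 under median-of-ratios scaling. Of 6 endosperm transcription factor genes 5 rose and 0 fell, which flipped to 1 higher and 5 lower under median-of-ratios scaling. Here the list's median and mean lay at -0.37 and -0.05 relative to all genes while camera pointed up (adjusted p = 0.77; adjusted p = 0.88 with an estimated correlation). NF-YB1 (LOC_Os02g49410), a CCAAT-binding subunit, rose 10.8-fold from 5.37 ± 1.61 to 58.2 ± 1.61 RPKM and also under median-of-ratios scaling (log2 fold change 1.98). NF-YC12 (LOC_Os10g11580), RISBZ1 (LOC_Os07g08420), a bZIP activator of storage protein genes, and NAC26 (LOC_Os01g29840) had log2 fold changes of 1.02, 0.87 and 0.43, which turned to -0.35, -0.49 and -0.94 under median-of-ratios scaling.

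OsTudor-SN itself (LOC_Os02g32350, chromosome 2, 19098854 to 19105533) read 91.1, 97.6 and 88.4 RPKM in wild type and 206, 212 and 221 RPKM in EM1084. The log2 fold change was 1.20 (SE 0.08, adjusted p = 1.2e-08), 0.13 above the median of all genes, and it turned to -0.17 (adjusted p = 0.02) under median-of-ratios scaling. Outside the lists, LOC_Os07g33997 was listed at 0 in every wild type library and at 616 ± 9.68 RPKM in EM1084, and LOC_Os01g72910 rose from 0.693 ± 1.08 to 313 ± 46.1 RPKM. LOC_Os12g12140 stood at 130 ± 6.47 RPKM in wild type and was listed at 0 in EM1084. In all, 13604 of 15450 genes were called, 12781 higher and 823 lower. Under median-of-ratios scaling 9118 were called, 5044 higher and 4074 lower, and 5043 genes were called higher and 823 lower both ways, while 1909 were called on opposite sides. Adjusted over the list alone, the counts of all 6 lists were those given. The control was a single set of 3 libraries of lower depth, and the source line of the wild type is not given in the sources used here.

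**Figure D3:**
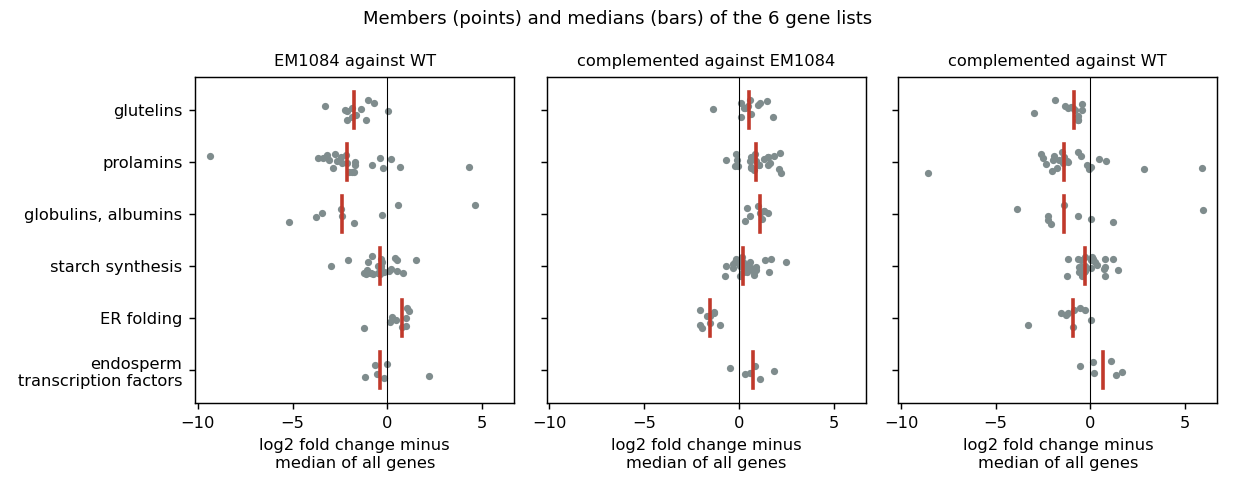
Log2 fold change minus the median of all genes (horizontal axis) of each member (points) of the 6 gene lists (vertical axis) in the 3 comparisons, with bars at the list medians. The ER folding list lay at 0.80 in EM1084 against wild type and at -1.53 in the complemented line against EM1084.

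The complemented line against EM1084 asked which transcripts move when a wild type OsTudor-SN copy is added to the mutant. The whole ER folding list was lower and most storage protein genes were higher, with glutelins flipping under quantile normalization. All 9 tested ER folding genes fell, as they did under quantile, median-of-ratios and outside-storage scaling, with a median of -1.53 relative to all genes (camera adjusted p = 2.4e-07; adjusted p = 0.092 with an estimated correlation, and 0.041 and 0.16 under median-of-ratios and outside-storage scaling). BiP1 fell 5.23-fold from 1640 ± 111 to 313 ± 28 RPKM (log2 fold change -2.39, SE 0.08, adjusted p = 4e-10). CNX (LOC_Os04g32950, calnexin, a lectin chaperone) fell from 248 ± 11.8 to 66.9 ± 1.18 RPKM, and PDIL1-1 fell from 2050 ± 164 to 561 ± 43.2 RPKM. Embryo and aleurone genes, markers of other parts of the seed, moved in the same comparison, with 5 of 10 higher, 0 lower and a median of 0.74 relative to all genes (camera adjusted p = 0.00013; adjusted p = 0.37 with an estimated correlation). Their share of the reads was 0.196% ± 0.017 in EM1084 and 0.22% ± 0.025 in the complemented line (exact permutation p = 0.3).

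**Figure D4:**
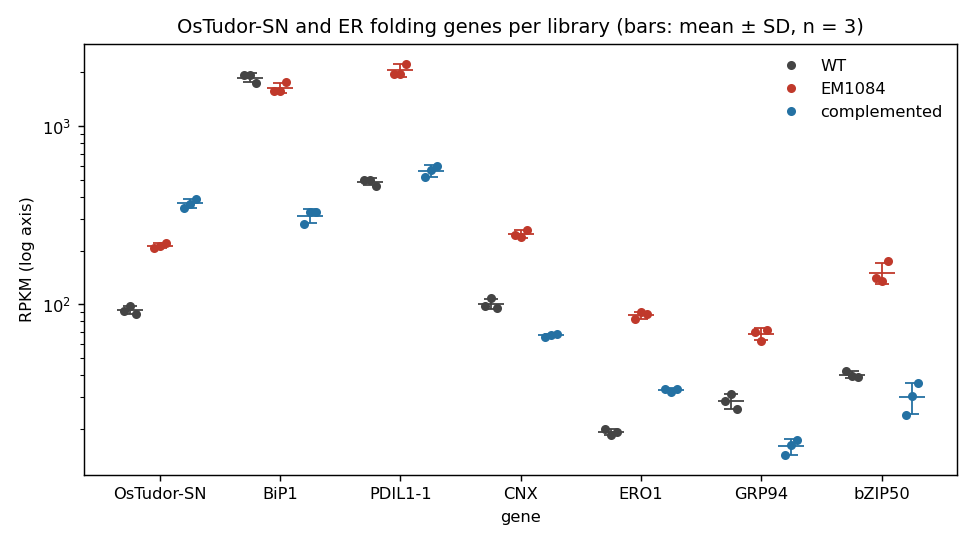
RPKM (log axis) of OsTudor-SN and genes of ER folding (horizontal axis) in every library, with points for libraries and bars for the mean ± SD of 3 libraries per genotype. BiP1 stood at 1870, 1640 and 313 RPKM and PDIL1-1 at 487, 2050 and 561 RPKM in wild type, EM1084 and the complemented line.

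Of 12 glutelin genes 6 rose and 3 fell (median 0.52 relative to all genes, camera adjusted p = 0.00071; adjusted p = 0.3 with an estimated correlation), which flipped to 2 higher and 6 lower under quantile normalization. GluA1 rose from 15400 ± 201 to 42800 ± 2220 RPKM (log2 fold change 1.47, SE 0.06, adjusted p = 1.4e-09), and GluA2 from 13900 ± 81.3 to 31200 ± 710 RPKM. LOC_Os02g14600, a glutelin locus, fell from 3490 ± 189 to 1070 ± 80.4 RPKM (log2 fold change -1.71, SE 0.08, adjusted p = 2.8e-09). It fell under median-of-ratios scaling too (-1.3). Of 23 prolamin genes 13 rose and 5 fell (median 0.89 relative to all genes, camera adjusted p = 8.2e-09; adjusted p = 0.0049 with an estimated correlation, lost under median-of-ratios scaling with 0.061 and outside the storage lists with 0.12), and LOC_Os07g10570 rose from 3670 ± 81 to 13100 ± 1020 RPKM. Among 9 globulin and albumin genes 7 rose and 0 fell (median 1.11 relative to all genes, camera adjusted p = 8.3e-08; adjusted p = 0.09 with an estimated correlation). RAG2 rose from 1480 ± 130 to 3380 ± 61.5 RPKM and alpha-globulin from 8250 ± 832 to 14100 ± 447 RPKM. More prolamin and globulin genes rose than fell under every scaling tried.

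Starch synthesis genes went both ways, with 10 higher and 8 lower of 25 (10 and 9 adjusted over the list alone, where the other 5 lists had the counts given), and a median of 0.23 relative to all genes (camera adjusted p = 0.0023; adjusted p = 0.3 with an estimated correlation). AGPL1 rose 4.71-fold from 19.1 ± 0.907 to 89.9 ± 11.4 RPKM (adjusted p = 2.9e-09), the isoamylase gene ISA1 (LOC_Os08g40930) from 200 ± 6.78 to 471 ± 12.9 RPKM, and the branching enzyme gene BEI (LOC_Os06g51084) from 873 ± 43.6 to 1770 ± 56.3 RPKM. AGPS2 stood at 2760 ± 125 and 2560 ± 157 RPKM (adjusted p = 0.23), a log2 fold change of -0.11 that turned to 0.31 under median-of-ratios scaling. Of 6 endosperm transcription factor genes 4 rose and 1 fell (median 0.72 relative to all genes, camera adjusted p = 0.00096; adjusted p = 0.17 with an estimated correlation). NAC20 (LOC_Os01g01470), a regulator of storage protein and starch genes, rose 2.9-fold from 242 ± 39 to 700 ± 53.9 RPKM, NF-YC12 rose from 462 ± 11 to 798 ± 47.3 RPKM and NAC26 from 409 ± 44.1 to 580 ± 48.4 RPKM. NF-YB1 fell from 58.2 ± 1.61 to 32.4 ± 3.46 RPKM.

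OsTudor-SN rose to 348, 367 and 389 RPKM in the complemented libraries (log2 fold change against EM1084 0.78, SE 0.08, adjusted p = 2.7e-06), and by 1.20 under median-of-ratios scaling. Outside the lists, LOC_Os07g06834 stood at 0.0352 ± 0.061 RPKM in EM1084 and 48.8 ± 13 in the complemented line, and LOC_Os03g02470 was listed at 0 in EM1084 and at 30.6 ± 2.05 RPKM in the complemented line. The neighbouring loci LOC_Os01g72900 and LOC_Os01g72910 fell from 358 ± 38.7 to 2.02 ± 0.558 RPKM and from 313 ± 46.1 to 1.72 ± 0.464 RPKM. In all, 8579 genes were called, 1573 higher and 7006 lower. Median-of-ratios scaling called 5720, 2798 higher and 2922 lower, and 1557 genes were called higher and 2922 lower both ways. A single transgenic line was profiled, so the transgene and other features of that line are not separated by this comparison.

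The complemented line against wild type asked what still differed after the transgene was added. Prolamin transcripts were lower, BiP1 was far lower than in either other genotype, and several endosperm regulators were higher. OsTudor-SN was 3.99-fold higher (368 ± 20.3 against 92.3 ± 4.73 RPKM, log2 fold change 1.98, SE 0.08, adjusted p = 4.2e-10), and 1.03 higher on the log2 scale under median-of-ratios scaling. Of 23 prolamin genes 14 fell and 6 rose (median -1.39 relative to all genes, camera adjusted p = 3.2e-11; adjusted p = 0.0034 with an estimated correlation). More fell than rose under every scaling tried, but with an estimated correlation the list's call was lost under median-of-ratios scaling (adjusted p = 0.074) and outside the storage lists (0.12). The prolamin loci with the smallest adjusted p rose. LOC_Os06g31060 went from 0.277 ± 0.259 to 123 ± 5.56 RPKM (log2 fold change 6.62, adjusted p = 1.5e-12). LOC_Os05g26440 went from 55.8 ± 8.52 to 663 ± 23.7 RPKM (3.56, adjusted p = 2.5e-11). Both rose under median-of-ratios scaling too (6.25 and 2.61). LOC_Os07g11910, next by adjusted p, fell from 25200 ± 681 to 6900 ± 477 RPKM (adjusted p = 1.2e-09). LOC_Os05g26377 was 41.8 ± 14.2 RPKM in the complemented line, again with the uncertain split of its reads (log2 fold change -7.83, or -7.17 without wild type 2 and -9.06 without wild type 3). Of 12 glutelin genes 5 fell and 2 rose (median -0.87 relative to all genes, camera adjusted p = 1.1e-06; adjusted p = 0.17 with an estimated correlation), which flipped to 7 higher and 2 lower under quantile normalization. GluB4 (LOC_Os02g16830) fell from 16200 ± 1340 to 11600 ± 837 RPKM, and GluA1 was 42800 ± 2220 against 34900 ± 2080 RPKM, a log2 fold change of 0.29 that turned to -0.67 under median-of-ratios scaling. Among 9 globulin and albumin genes 5 fell and 3 rose (median -1.38 relative to all genes, camera adjusted p = 8.4e-05; adjusted p = 0.17 with an estimated correlation), which flipped to 4 higher and 3 lower under quantile normalization. RAG1 rose to 553 ± 12.2 RPKM and REG2 (LOC_Os03g46100) rose from 197 ± 15.9 to 749 ± 39.8 RPKM, while alpha-globulin stood at 13300 ± 792 and 14100 ± 447 RPKM (log2 fold change 0.08, adjusted p = 0.35, turning to -0.88 under median-of-ratios scaling).

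Of 9 ER folding genes 4 fell and 3 rose against wild type, with a median of -0.94 relative to all genes (camera adjusted p = 2.5e-05; adjusted p = 0.16 with an estimated correlation). Under median-of-ratios scaling 8 were lower and 0 higher. BiP1 fell 5.97-fold from 1870 ± 106 to 313 ± 28 RPKM (log2 fold change -2.58, SE 0.08, adjusted p = 1.1e-10), and GRP94 (LOC_Os06g50300), an ER chaperone of the HSP90 family, from 28.6 ± 2.8 to 15.9 ± 1.57 RPKM. ERO1 was 33.1 ± 0.704 against 19.2 ± 0.731 RPKM, a log2 fold change of 0.75 that turned to -0.17 under median-of-ratios scaling. PDIL1-1 was 561 ± 43.2 against 487 ± 22.6 RPKM (log2 fold change 0.20, adjusted p = 0.037), and turned to -0.76 under median-of-ratios scaling. Its call was also lost without wild type 1 (adjusted p = 0.058), wild type 2 (0.054), wild type 3 (0.12), complemented 2 (0.094) or complemented 3 (0.13).

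Of 25 starch synthesis genes 19 rose and 2 fell, which flipped to 6 higher and 14 lower under median-of-ratios scaling. Their median and mean lay at -0.26 and -0.01 relative to all genes while camera pointed up (adjusted p = 0.26; adjusted p = 0.67 with an estimated correlation), and the median moved to -0.15 without EM1084 2 or EM1084 3 and to -0.10 without complemented 3. SUS3, ISA1 and AGPS1 (LOC_Os09g12660, a small subunit of ADP-glucose pyrophosphorylase) rose to 225 ± 9.19, 471 ± 12.9 and 159 ± 3.75 RPKM from 48.9 ± 1.3, 166 ± 14.5 and 56.9 ± 4.28 RPKM, and did so under median-of-ratios scaling as well (log2 fold changes 1.22, 0.54 and 0.52). AGPS2 did not pass (log2 fold change 0.12, adjusted p = 0.15), passed without complemented 1 (0.17, adjusted p = 0.039), and turned to -0.85 under median-of-ratios scaling. Of 6 endosperm transcription factor genes 5 rose and 0 fell (median 0.64 relative to all genes, camera adjusted p = 0.032; adjusted p = 0.32 with an estimated correlation), and 3 were higher and 1 lower under median-of-ratios scaling, where the list did not pass (camera adjusted p = 0.25). NAC20 rose 4.19-fold from 167 ± 7.41 to 700 ± 53.9 RPKM (adjusted p = 4.3e-09), NF-YC12 3.51-fold from 227 ± 11.5 to 798 ± 47.3 RPKM, and NF-YB1 6.03-fold from 5.37 ± 1.61 to 32.4 ± 3.46 RPKM. NAC26 was 580 ± 48.4 against 302 ± 28.8 RPKM, a log2 fold change of 0.94 that turned to -0.02 under median-of-ratios scaling. Outside the lists, LOC_Os07g33997 and LOC_Os09g32169 were listed at 0 in wild type and stood at 358 ± 33.1 and 184 ± 9.45 RPKM in the complemented line, and LOC_Os12g12140 fell from 130 ± 6.47 to 0.0796 ± 0.138 RPKM. In all, 12263 genes were called, 11124 higher and 1139 lower, and 8457 under median-of-ratios scaling, 4597 higher and 3860 lower. Both ways, 4597 were called higher and 1139 lower, and 911 were called on opposite sides. Adjusted over the list alone, the counts of all 6 lists were those given.

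A last comparison asked how far the expression of genes changed in EM1084 lay back toward wild type in the complemented line. Of the 13604 genes called between EM1084 and wild type, 6930 (50.9%) were called in the opposite direction between the complemented line and EM1084, and the median share of the change remaining was 67.2% (quartiles 42.9% and 91%). Simulated data gave 0.00146% called back and 99.6% remaining with the complemented line set equal to EM1084, and 97.2% called back and 0.387% remaining with it set equal to wild type. The simulations used RPKM as deposited. Under median-of-ratios scaling 3322 of 9118 genes were called back (36.4%) with 72.3% remaining, and under scaling outside the storage lists 3689 of 11164 (33%) with 76.4% remaining. Genes called still further from wild type numbered 837 (6.2%) as deposited. They numbered 845 (9.3%) under median-of-ratios scaling and 942 (8.4%) outside the storage lists. GluA1, GluA2, RAG2, AGPL1 and PDIL1-1 were among the genes called back, under median-of-ratios scaling too. A gene called back need not end nearer to wild type. Under median-of-ratios scaling PDIL1-1 went past it, with log2 fold changes against wild type of 0.69 in EM1084 and -0.76 in the complemented line. Across genes, the changes of the 2 lines against wild type had a Pearson r of 0.68 (covariance 0.51), against 0.5 (covariance 0.0148) in simulations with all genotypes equal, which the shared wild type libraries alone produce; genes are not independent replicates. Both lines were called higher for 10393 genes and lower for 529, against 9202 and 61 if the calls were independent, and 391 were called on opposite sides. Under median-of-ratios scaling the balance differed, with 3103 higher and 2884 lower in both, against 1501 and 1018 if independent, and 402 on opposite sides. The independent numbers leave the shared wild type libraries out of account.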

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

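Both tests below on the ER folding list were chosen after the result was seen. The ER folding and quality control list stood out because its change against wild type pointed up in EM1084 (median 0.80 relative to all genes, 0.53 without EM1084 3 and 0.40 under median-of-ratios scaling, camera adjusted p = 0.074, which did not pass) and down in the complemented line (-0.94, adjusted p = 2.5e-05; adjusted p = 0.16 with an estimated correlation). The difference itself, tested as the complemented line against EM1084, was -1.53 (camera adjusted p = 2.4e-07; adjusted p = 0.092 with an estimated correlation), with 9 of 9 members lower. Scaling between libraries is argued against as the cause, since 9 of 9 members were called lower under each of quantile, median-of-ratios and outside-storage scaling. Less storage-protein-making tissue in the complemented seeds would go with lower storage lists there. More prolamin genes rose than fell under every scaling tried (median 0.89 relative to all genes). With an estimated correlation the prolamin call (adjusted p = 0.0049) was lost under median-of-ratios (0.061) and outside-storage scaling (0.12). The lowest median of a storage list was 0.52, that of glutelins, whose direction flipped under quantile normalization (2 higher, 6 lower). The glutelin call was lost with an estimated correlation (adjusted p = 0.3). Storage transcripts themselves differed among the genotypes, so they do not separate the amount of tissue from expression per cell. These values therefore cannot decide whether there was less of that tissue. Embryo and aleurone genes also lay higher (0.74, camera adjusted p = 0.00013; adjusted p = 0.37 with an estimated correlation), so another mix of seed tissues, the transgene, with OsTudor-SN at 368 RPKM against 213 in EM1084, and other features of the single transgenic line may each lie behind the fall and were not tested apart.

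The endosperm transcription factor list stood out in the same way, with medians relative to all genes, each against wild type, of -0.37 in EM1084, which did not pass (mean -0.05 while camera pointed up, adjusted p = 0.77), and 0.64 in the complemented line (camera adjusted p = 0.032, lost with an estimated correlation, adjusted p = 0.32, and under median-of-ratios scaling, adjusted p = 0.25), and a tested difference of 0.72 (camera adjusted p = 0.00096; adjusted p = 0.17 with an estimated correlation).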

How the results depend on the processing

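Chosen after seeing the data were limma-voom on derived reads, thinned reads, estimated correlations under each scaling, the prolamin list without the overlapping pair (same calls in all 3 comparisons) and median-of-ratios scaling of the gene counts. In what follows values are in the order median-of-ratios scaling, library size outside the storage lists and voom, and the cause of these changes was not tested.

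For EM1084 against wild type, OsTudor-SN reversed under median-of-ratios scaling and voom (-0.17 in both). Reversed genes were AGPS2 (-1.15, -0.47, -1.16), NAC26 (-0.94, -0.25, -0.95), and, under median-of-ratios scaling and voom alone, NF-YC12 (-0.35, -0.36) and RISBZ1 (-0.49, -0.50; 0.19 and no longer called outside the storage lists). LOC_Os02g15169 gained a call as lower (-1.45, -0.76, -1.46). The camera direction of the endosperm transcription factor list turned from up to down (adjusted p = 0.015, 0.22 and 0.0048), its median relative to all genes staying below 0 (-0.77, -0.57, -0.81, against -0.37), and the starch list passed as lower (-0.68, -0.54, -0.77). With an estimated correlation the starch list had camera adjusted p values of 0.041, 0.35 and 0.03, so its call was lost outside the storage lists. For the complemented line against EM1084, AGPS2 reversed (0.31, 0.22, 0.31). For the complemented line against wild type, GluA1 (-0.67, -0.07, -0.67), alpha-globulin (-0.88, -0.28, -0.89), AGPS2 (-0.85, -0.25, -0.85) and PDIL1-1 (-0.76, -0.16, -0.76) reversed, as did, under median-of-ratios scaling and voom alone, ERO1 (-0.17, -0.18) and NAC26 (-0.02, -0.03). The camera direction of the starch list turned from up to down (adjusted p = 0.035, 0.74 and 0.019), its median staying below 0 (-0.36, -0.39, -0.58, against -0.26), and the endosperm transcription factor list no longer passed (0.31, 0.51, 0.29). Genes called back by complementation numbered 3322, 3689 and 3944, with 72.3%, 76.4% and 72.5% of the change remaining.

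With an estimated correlation no list passed outside the storage lists, where the lowest adjusted p was 0.061. Prolamins had adjusted p values of 0.041, 0.061 and 0.03 in EM1084 against wild type (0.00071 as reported), 0.061, 0.12 and 0.043 in the complemented line against EM1084 (0.0049) and 0.074, 0.12 and 0.043 in the complemented line against wild type (0.0034). Lists that gained a call that way were, in EM1084 against wild type, starch (0.041, 0.35, 0.03; 0.64 as reported), transcription factors (0.098, 0.56, 0.044; 0.88) and glutelins (0.11, 0.18, 0.044; 0.075). In the complemented line against EM1084 they were ER folding (0.041, 0.16, 0.03; 0.092), starch (0.041, 0.35, 0.03; 0.3), transcription factors (0.041, 0.23, 0.03; 0.17) and globulins (0.061, 0.19, 0.044; 0.09), and in the complemented line against wild type glutelins (0.12, 0.2, 0.047; 0.17) and ER folding (0.061, 0.19, 0.043; 0.16). The starch list of the last comparison did not pass (0.11, 0.91, 0.087; 0.67).

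Counts moved by over 1.5 times for EM1084 against wild type under quantile normalization (8679), voom (8322) and the 2-fold limit (8670), for the complemented line against EM1084 under that limit (2283), and for the complemented line against wild type under quantile normalization, voom and the 2-fold limit (8052, 7641 and 5460). The counts stayed within 1.5 times without a filter (16214, 8909, 13514 and 17221 for the 3 comparisons and the joint test), with a pseudocount of 0.1 (13528, 7413, 12224 and 14192) and with 6 libraries only (13054, 9180 and 11066). An edgeR fit was planned for deposited counts, with limma as the choice for a table without counts. A DESeq2 fit outside this plan was tried on the derived reads, and its values are not given because the deposited unit is RPKM. With replicate block, numbers in the labels treated as if paired, the counts were 13595, 8395, 12166 and, for the joint test, 14351, with 6774 called back and 67.2% remaining, and BiP1 in EM1084 against wild type alone lost its call among 76 values of named genes. Correlations of replicate deviations lay between -0.03 and 0.06 for same-numbered libraries and between -0.08 and 0.08 for the others. No pairing by number showed, but such correlations cannot exclude it.

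Leaving out each library in turn gave 12609 to 13530 genes for EM1084 against wild type, 7045 to 9004 for the complemented line against EM1084, 11169 to 11874 for the complemented line against wild type and 13512 to 14132 jointly, with 5593 to 7184 called back and 64.5% to 69.8% remaining. With the preset correlation no list changed its call, but the median of the ER folding list in EM1084 against wild type fell from 0.80 to 0.53 without EM1084 3, and that of the starch list in the complemented line against wild type moved from -0.26 to -0.10 without complemented 3 and to -0.15 without EM1084 2 or EM1084 3. OsTudor-SN ranged from 1.17 to 1.24, 0.74 to 0.82 and 1.94 to 2.02. Depth limits the wild type most, where 1 read at 1 kb was up to 0.173 RPKM. Thinned to 5352085 reads per library, the counts were 13179, 7670, 11472 and 13928.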

Other observations

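The tests of storage and abundant transcripts below were chosen after the result was seen, and the lists of this part were written after the table was opened but before their values were looked at. Single genes named from these lists were not chosen by the rule for named genes. Embryo and aleurone genes went both ways. In EM1084 the oleosin gene OLE18 (LOC_Os03g49190), which encodes a coat protein of oil bodies, rose from 66.5 ± 2.84 to 986 ± 83.2 RPKM (log2 fold change 3.87, adjusted p = 1.8e-11) and stood at 876 ± 149 RPKM in the complemented line. The dehydrin genes Rab16B (LOC_Os11g26780) and Rab16C (LOC_Os11g26760), which respond to abscisic acid, fell from 236 ± 26.5 to 4 ± 0.739 RPKM and from 62.9 ± 8.84 to 2.54 ± 0.192 RPKM, and Rab16B was 15.9 ± 1.1 RPKM in the complemented line (adjusted p = 1.1e-10 against wild type). Of 10 tested members 6 rose and 4 fell in EM1084 against wild type, with a median of -0.59 relative to all genes (camera adjusted p = 0.00013; adjusted p = 0.37 with an estimated correlation), and 2 rose and 6 fell under median-of-ratios scaling. In the complemented line against EM1084 5 rose and 0 fell, with a median of 0.74 relative to all genes (camera adjusted p = 0.00013; adjusted p = 0.37 with an estimated correlation), and in the complemented line against wild type 5 rose and 4 fell (-0.25, camera adjusted p = 0.012; adjusted p = 0.68 with an estimated correlation). Green tissue genes were barely detected, with at most 2.46 RPKM in any genotype and 3 of 15 loci tested, and of the alpha-amylases the 1 tested locus had a highest group mean of 7.77 RPKM.

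Among 12 heat shock protein genes 8 rose and 1 fell in EM1084 against wild type (median 0.18 relative to all genes while camera pointed down, adjusted p = 0.55), which became 6 and 6 under median-of-ratios scaling. HSP16.9A (LOC_Os01g04370) rose from 19 ± 1.32 to 160 ± 16.6 RPKM, and HSP16.9B (LOC_Os01g04380), its neighbour, fell from 13.5 ± 1.43 RPKM in EM1084 to 0.51 ± 0.0488 in the complemented line (adjusted p = 1.3e-08). Of 7 genes of glutelin trafficking and processing 6 rose and 1 fell (camera adjusted p = 0.67), which became 1 and 2 under median-of-ratios scaling. SAR1A (LOC_Os01g23620), a GTPase of vesicles leaving the ER, rose from 5 ± 0.443 to 38.4 ± 1.86 RPKM in EM1084 and fell to 12.8 ± 1.82 RPKM in the complemented line, in the same directions under median-of-ratios scaling (log2 fold changes 1.46 and -1.11). Cell division (4 of 5 higher, 0 lower), gibberellin (7 of 7 higher) and control genes (7 of 8 higher, 1 lower) did not pass as lists (camera adjusted p = 0.67, 0.55 and 0.55). Under median-of-ratios scaling 2, 2 and 2 of them were higher and 0, 2 and 4 lower, the control genes thus flipping. GAPDH (LOC_Os04g40950), a control gene, rose from 26 ± 2.22 to 146 ± 6.36 RPKM.

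Most genes were higher in RPKM in EM1084 than in wild type, with a median log2 fold change of 1.06. A larger share of storage protein transcripts in wild type is argued against as the whole cause, since the median stayed at 0.58 after scaling on the reads outside those lists. The 144 genes among the 100 most abundant of any library took 77.3%, 50.4% and 63.4% of the reads in wild type, EM1084 and the complemented line. Leaving them out lowered the median to 0.28, so these 144 genes may account for part of the shift but not all of it. The 500 most abundant genes of each library took 83.7%, 61.1% and 71.9% in the same order. A wider cut was not tried, so the 0.28 left does not show a shift beyond the share of abundant genes. Counting error from lower wild type depth is argued against, because the median was 1.06 with every library thinned to the smallest. RPKM is relative to the mapped total, so thinning could move this median through counting error alone. It does not test whether reads that are not independent fragments play a part. Whether the mutant seeds held more RNA of most genes per cell, or the wild type seeds were at another stage within the sampled days, stays open and was not tested.

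Loci with at least 5 RPKM in every library on one side and under 0.1 RPKM in every library on the other numbered 20 between wild type and both other lines (4 on in wild type alone, 16 off in wild type alone), against 2 that set EM1084 apart and 3 that set the complemented line apart. This count is consistent with a genetic background shared by EM1084 and the complemented line and differing from that of the wild type. A single linked segment is argued against, as the 20 loci lay on 8 chromosomes with 25% on chromosome 4, and 2 had another within 200000 bases (permutation p = 0.23). An effect of the mutation that the transgene did not reverse stays open. Depth affects which loci fall under 0.1 RPKM, since 1 read at 1 kb was worth up to 0.173 RPKM in wild type and up to 0.078 in the other lines. Whether this makes loci off in wild type easier or harder to list was not tested. The limits were also set on RPKM as deposited, where the median log2 fold change against wild type was 1.06 in EM1084 and 0.73 in the complemented line. Loci may thus pass as on more easily in these lines and as off more easily in wild type. The loci were not counted under another scaling.

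As to other splits of the libraries, the 3 pairwise comparisons each allow 10 splits, too few for a share under 0.05. The real split was the 1 with the most called genes in each, with 13604, 8579 and 12263 genes, and the highest other split called 0 in each. For the joint test, 1 of 100 splits drawn from 280 reached the real 14368 genes, the real split itself, and the highest other called 10416. A random split is thus an unlikely source of that count on RPKM as deposited, but it is not excluded. Under median-of-ratios scaling the real split called 10765 genes, and other splits were not counted there.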
